A study of Mus musculus with 48 samples.

How the data were processed

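H3K27ac and input libraries were made from forebrain, heart and liver of CD-1 mice at 7 stages. Per the labels' protocols, tissue was cross-linked and sonicated, immunoprecipitation used an antibody to H3K27ac, libraries were made with the Illumina TruSeq kit with index barcodes, and material was pooled from several animals except at P56. BWA, MACS 1.4 and the mouse build mm9 are named in the submitters' processing notes. Their roles and other parameters are not given in the sources used here. The authors deposited 1 list of peaks per library, called per library. Per the file headers, the track names of the H3K27ac lists include the words withInput and pe05, and each line gives a position and the authors' rank of the peak in its list, with no score. A deposited summary table gives, as read counts and peak counts per library, filtered reads, uniquely mapped reads and the number of peaks. Its peak number exceeded that of the H3K27ac list in every library, by 1 at liver E11.5, by 5133 at liver P21 and by 16476 at heart P21 (23852 against 7376); the filter between them is not stated in the sources used here. A rank was used only within its own list.

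Groups were taken from the sample labels and rows of the summary table were matched to samples by tissue, stage, mark and replicate. Peaks that overlapped by at least 1 bp over the 24 H3K27ac lists were merged into elements, and an element counted as marked in a list that had a peak in it. Peak lists record presence only, so tests were exact permutation tests on the Jaccard index, counts over splits of the lists, and an exact test per element. The main results used 21 lists, 1 per tissue and stage, with replicate 1 where a group had 2. Tissue separation permuted tissue labels within stages (two-sided). Stage ordering compared adjacent with other stage pairs over all orders of the stages (one-sided). Turnover compared replicate pairs with adjacent pairs (one-sided). Restriction of an element to a tissue was tested with stage as a stratum, one-sided, with Benjamini-Hochberg adjustment over elements with a peak in the tissue and over the 3 tissues, called at 0.05. Intervals are exact Clopper-Pearson intervals at 95%. The correlations with depth used log2 of uniquely mapped reads and 100000 resamples. Coordinates are 1-based mm9 positions.

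Designs, alternatives and the rule for named elements were fixed before the data were examined. The rule takes, per tissue, the 5 prenatal-only, 5 postnatal-only and 5 restricted elements with the highest mean within-list rank percentile (100 for the best peak), ties by position, and the 5 windows of 100 kb with the most restricted elements. The rule was written for a peak score, and the authors' rank stood in for it here and in choosing the best peaks for equal list lengths. The other settings fixed then were equal list lengths, peaks trimmed to 1 kb, a 50% overlap of the shorter interval, leaving out P21 or heart P21, replicate 2 in place of replicate 1, peaks in both or either replicate, removal of peaks overlapping input peaks, autosomes only, base-pair Jaccard, Fisher's exact test, and replicate number as a block. Comparisons by library name series, depth, number of stages or tissues, rank, and prenatal to postnatal separation between tissues were chosen after the data were seen.

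The restriction tests were checked on simulated data with the tissue labels of each of 85254 elements permuted within stages; with none planted, both tests called 0. With 2000 elements planted per tissue, at all stages of 1 tissue and none of the others, the stratified test recovered 100% with 17 other calls and Fisher's exact test 100% with 108. With 200 planted per tissue the stratified test recovered 0%, and Fisher's exact test 100% with 17 other calls. Every planted element took the smallest p that the stratified test can give, so that its recovery was set by the number planted. In the real lists 889 elements had that p. Recovery of weaker patterns was not simulated. The ordering test found 100% of 200 simulated drifting series and called 4 of 200 without drift. These series did not copy the unequal lengths of the real lists.

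No mm9 gene annotation was used here, and coordinates were not converted between builds. Comparisons of promoter with distal peaks, peaks linked to genes, and the 21 gene and cell type lists planned were therefore not run, and elements are named by position alone. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.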

Results

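Histone H3 acetylated at lysine 27 (H3K27ac), a mark of active enhancers and promoters, was profiled by chromatin immunoprecipitation and sequencing in forebrain, heart and liver of CD-1 mice. The design asks how the set of marked regions changes with tissue and with developmental stage. Tissue was taken at 7 stages, embryonic days E11.5, E14.5 and E17.5 and postnatal days P0, P7, P21 and P56, and was pooled from several animals at every stage except P56. Each of the 24 H3K27ac libraries had an input library of DNA taken before immunoprecipitation, which makes 48 libraries in all. Forebrain E11.5, forebrain P56 and heart E11.5 had 2 replicates, and the other 18 tissue and stage groups had 1 library of each kind. In the authors' deposited table and in the headers of the peak lists themselves, P0 is written as P1 and P21 as P20. The stage names of the sample labels are used here, and which is right is not known.

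The H3K27ac libraries held between 4108135 uniquely mapped reads, at liver P0, and 33394166, at forebrain E14.5. Their peak lists held between 7376 peaks, at heart P21, and 39133, at heart P0. The number of peaks did not follow depth detectably over the 24 lists, with a Pearson r of 0.200 (permutation p = 0.346) and a Spearman rho of 0.133 (permutation p = 0.534). Without the 2 lists farthest from the median depth, r was -0.117 (permutation p = 0.603). Library names in the file headers form 2 series, which may be batches: 11 H3K27ac libraries named IO, with a median of 75.4% of filtered reads mapped uniquely, and 13 named LPAN, with 27.4%. Within these, r was 0.203 over the 11 lists (permutation p = 0.544) and 0.300 over the 13 lists (permutation p = 0.317). All forebrain libraries except the P56 replicate 2 pair, both heart E11.5 pairs and the heart P56 pair belong to the first series, and the others, with all of liver, to the second.

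**Figure D1:**
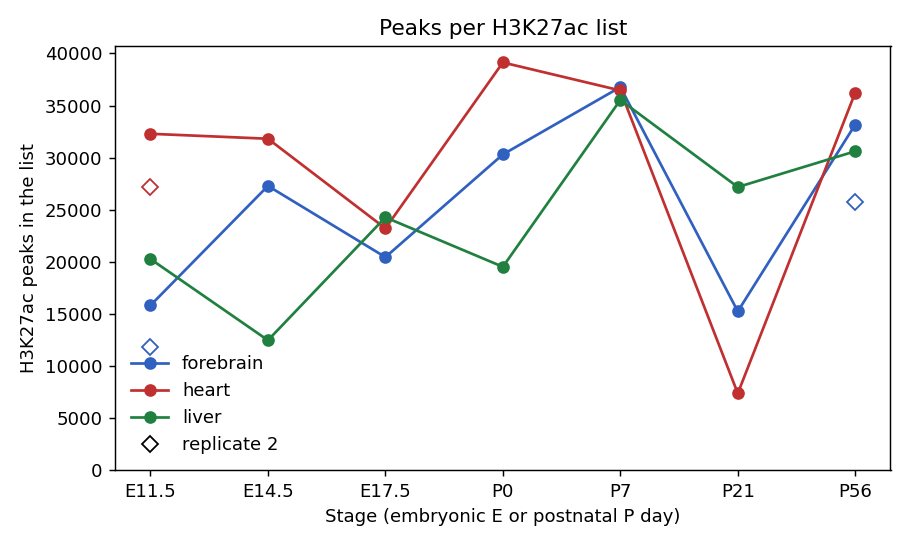
Number of H3K27ac peaks per list (vertical axis) by stage (horizontal axis), with filled circles joined by lines for replicate 1 and open diamonds for replicate 2. The heart P21 list, with 7376 peaks, is the shortest, and the heart P0 list, with 39133, the longest.

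Merging overlapping peaks of the 24 lists gave 86181 elements with a median width of 2956 bp. Among elements with a peak in at least 1 of the 21 lists of replicate 1, 49328 (57.9%) were marked in a single tissue, 17373 (20.4%) in 2 tissues and 18553 (21.8%) in all 3. Elements seen in forebrain alone numbered 20534, against 15966 for heart and 12828 for liver. These numbers were not matched for list length or library series. Marking in a single tissue can rest on 1 list. Between the forebrain E11.5 replicates, 4419 elements were marked in replicate 1 alone. Lists of the same tissue at different stages shared more elements than lists of different tissues, with a mean Jaccard index (shared elements divided by all elements of both lists) of 0.488 within a tissue and 0.319 between tissues. The difference of 0.169 gave p = 2.14e-05 in a two-sided exact permutation test of tissue labels within stages, the smallest p that the 46656 relabellings can give. Within the LPAN series, heart and liver at 5 stages had a difference of 0.159 (exact p = 0.0625, the smallest that 16 relabellings can give). Forebrain and heart in the IO series could be compared at only 2 stages, with a difference of 0.0651 (exact p = 0.5, the smallest that 2 relabellings can give).

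**Figure D2:**
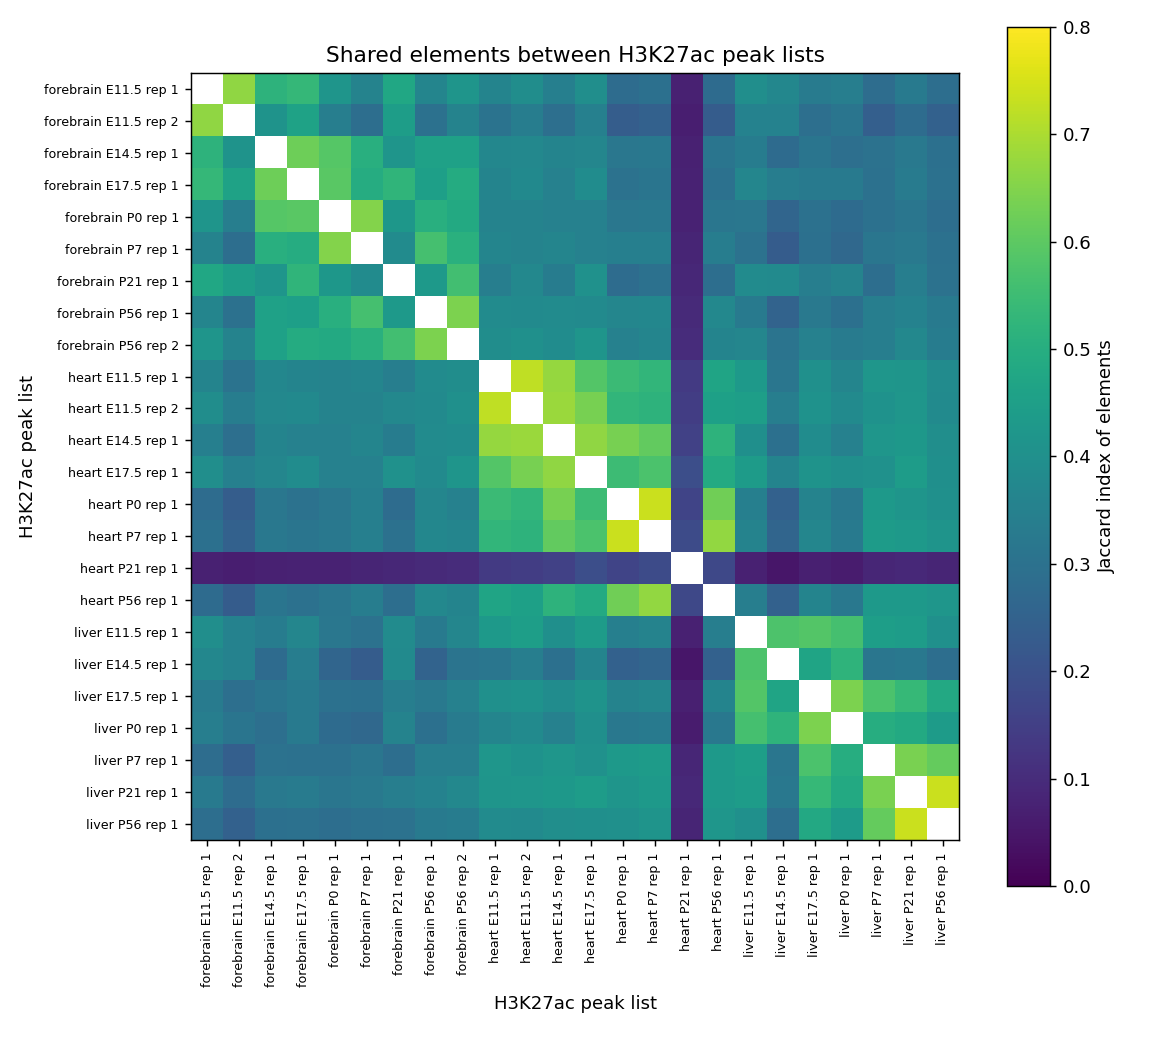
Jaccard index of shared elements (colour scale) for every pair of the 24 H3K27ac lists, ordered by tissue and stage along both axes, with each list's pair with itself left blank. Over the 21 lists of replicate 1 the mean was 0.488 within a tissue and 0.319 between tissues, and the heart P21 list stands out as a dark row and column.

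Tissue-restricted elements were sought by testing, element by element, whether peaks fell in 1 tissue more often than in the others at the same stages. Elements marked at all 7 stages of 1 tissue and in none of the 14 lists of the other tissues numbered 386 in forebrain, 425 in heart and 78 in liver. Without P21 in every tissue, those marked at all 6 remaining stages and in none of the other tissues numbered 738, 928 and 93. The planned exact test stratified by stage, with Benjamini-Hochberg adjustment over 139733 tests, called 0 elements in forebrain, 0 in heart and 0 in liver; the lowest adjusted p was 0.061. At an unadjusted p under 0.05 it found 8876, 10053 and 6423 elements. Fisher's exact test without the stage stratum, planned as an alternative, called 2890 elements in forebrain, 3024 in heart and 1524 in liver. Fisher's exact test called 2629, 3068 and 734 with stage P21 left out, a combination chosen after seeing the data. Without peaks that overlap a peak of any input list, which left 101735 tests, the stratified test called 1377 elements in forebrain, 1417 in heart and 58 in liver. With the heart P21 input list left out of that filter, chosen after seeing the data, it called 0, 0 and 0, with 8885, 10073 and 6425 elements at an unadjusted p under 0.05. The stratified test cannot give a p below 0.000457. Neither test separates tissue from library series, since the forebrain lists used are all IO and the liver lists all LPAN.

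Since the planned test called none, the restricted elements named here are those marked at all 7 stages of 1 tissue and in no other tissue. This choice was made after the counts were seen. An element takes the rank of its best peak in each list, and peaks of different stages can lie apart within a wide element. The 5 forebrain elements below were 25247 to 58729 bp wide, against a median of 2956 bp over all elements. The elements with the highest mean rank in the authors' lists are given, in mm9 coordinates. In forebrain they lay on chromosome 3 from 87998018 to 88048602, chromosome 3 from 17681814 to 17707060, chromosome 12 from 50471302 to 50506613, chromosome 7 from 86638103 to 86696831 and chromosome 14 from 65188831 to 65218325. The first of these had a mean rank percentile of 97.9 over the 7 lists. In heart they lay on chromosome 1 from 137725306 to 137745951, chromosome 9 from 110662916 to 110670955, chromosome 11 from 58949199 to 58954400, chromosome 15 from 96929874 to 96937072 and chromosome 18 from 65547910 to 65560081, with a percentile of 95.8 for the first; each of them needed a peak in the short heart P21 list. In liver they lay on chromosome 1 from 90100100 to 90126753, chromosome 5 from 44608114 to 44621521, chromosome 19 from 10727735 to 10741110, chromosome 11 from 120755646 to 120767597 and chromosome 17 from 84229806 to 84250642, with a percentile of 94.4 for the first. For the same reason, windows of 100 kb were ranked by the number of elements called by Fisher's exact test in place of the planned test. In forebrain, 5 windows held 5 such elements each, and they started at 31900001 on chromosome 11, 45500001 on chromosome 12, 179500001 on chromosome 2, 45400001 on chromosome 9 and 162700001 on chromosome X. In heart, the windows starting at 68400001 on chromosome 11 and 47500001 on chromosome 14 held 6, those at 191700001 on chromosome 1 and 137700001 on chromosome 3 held 5, and that at 30900001 on chromosome 10 held 4. In liver, the window starting at 31600001 on chromosome 13 held 4, and those at 7900001 and 104800001 on chromosome 12, 94400001 on chromosome 13 and 29800001 on chromosome 14 held 3 each.

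Part of the marked regions of each tissue was found at a single stage. In forebrain, 8694 elements were marked at all 7 stages and 15202 at a single stage, out of 48237 marked at any stage. In liver the numbers were 7922 and 10762 of 41817. In heart, 3368 elements were marked at all 7 stages and 12794 at a single stage, of 49679; without P21, a choice made after seeing the data, 15472 of 49586 were marked at all 6 remaining stages. Elements marked at all 7 stages of a tissue held a higher median rank than elements marked at a single stage in 21 of 21 lists, with median rank percentiles from 60.2 to 86.8 against 10.2 to 24.8. Part of this is built in, since the lowest ranked peaks are the likeliest to be missed in other lists. An element also took the rank of its best peak. Between the forebrain E11.5 replicates, 4419 elements were marked in replicate 1 alone, so that marking at a single stage need not mean stage specificity.

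Neighbouring stages shared more elements than distant ones in liver and forebrain. The mean Jaccard index of the 6 adjacent stage pairs in liver was 0.593, against 0.467 for the 15 other pairs (exact one-sided permutation p = 0.00952 over 5040 orders). The lists used belong to 1 library series in liver and 1 in forebrain. In forebrain the means were 0.534 and 0.472, a difference of 0.0621 (exact one-sided permutation p = 0.0413). Without P21 the difference was 0.122 (exact p = 0.00556), and with equal list lengths 0.128 (exact p = 0.000397, the smallest that the orders can give). The call was lost with E11.5 replicate 2 in place of replicate 1 (exact p = 0.0504) and where a peak had to cover 50% of its element (exact p = 0.0984), the latter chosen after seeing the data. In heart the means were 0.497 and 0.459 (exact one-sided permutation p = 0.256). Without the heart P21 list, whose Jaccard index with its neighbours was 0.183 and 0.172, the heart values were 0.659 and 0.557 (exact p = 0.00556 over 720 orders). Within the LPAN series, the 5 heart stages from E14.5 to P21 gave 0.533 against 0.388 (exact p = 0.117), and the 4 without P21 gave 0.650 against 0.605 (exact p = 0.333, where 24 orders cannot give a p below 0.0833).

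The share of peaks kept from 1 stage to the next was compared with that between replicates. From P0 to P7, 91.8% (exact binomial 95% interval 91.4 to 92.2) of liver P0 peaks overlapped a P7 peak, while 48.7% (48.2 to 49.2) of P7 peaks overlapped a P0 peak. The P7 list added 15039 elements and lost 1058. From E14.5 to E17.5, liver added 11267 elements and lost 869. The Jaccard index was 0.497 from P0 to P7 and 0.467 from E14.5 to E17.5. Other liver transitions went the other way: E11.5 to E14.5 added 786 and lost 7067, and E17.5 to P0 added 1780 and lost 6702. In forebrain, E11.5 to E14.5 added 11753 elements and lost 1068, and E14.5 to E17.5 added 1786 and lost 8505. Forebrain P7 to P21 added 516 and lost 20306, and P21 to P56 added 16790 and lost 428. In heart, E14.5 to E17.5 added 912 and lost 8632, and E17.5 to P0 added 15360 and lost 630. Around the short heart P21 list, P7 to P21 added 482 and lost 25855, and P21 to P56 added 27829 and lost 487. Between the replicates of forebrain E11.5, 68.7% (68.0 to 69.5) of the peaks of replicate 1 overlapped replicate 2, and 92.0% (91.5 to 92.5) the other way, so that the same asymmetry arose between lists of 15823 and 11871 peaks of 1 group. Intervals cover counting error only.

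The mean Jaccard index of the 3 replicate pairs was 0.678 ± 0.042 (SD, n = 3) and that of the 18 adjacent stage pairs 0.541 ± 0.165 (SD, n = 18). The difference of 0.137 did not pass the threshold (exact one-sided permutation p = 0.0541 over 1330 choices of 3 pairs), and since pairs share lists this p is descriptive. It was 0.0753 without P21 (exact permutation p = 0.0551) and 0.0793 with equal list lengths (exact permutation p = 0.201). It passed with peaks trimmed to 1 kb (0.149, exact permutation p = 0.0256) and without peaks overlapping any input peak (0.162, exact permutation p = 0.0195), but not with the heart P21 input list left out of that filter (0.137, exact permutation p = 0.0526). Within 1 library series, 2 replicate pairs averaged 0.696 and 16 adjacent pairs 0.556 (exact permutation p = 0.0588).

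**Figure D3:**
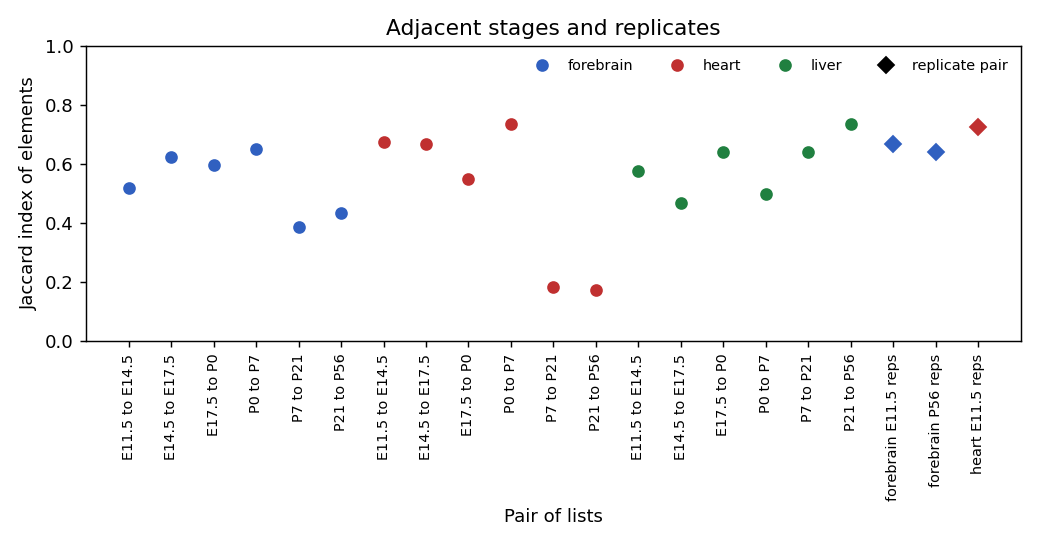
Jaccard index of shared elements (vertical axis) for the 18 adjacent stage pairs (circles) and the 3 replicate pairs (diamonds), coloured by tissue. The replicate pairs lie at 0.667, 0.641 and 0.724, and the pairs with heart P21 at 0.183 and 0.172.

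Forebrain E11.5 and P56 are the only stages of 1 tissue with 2 replicates each. Replicates had a mean Jaccard index of 0.654 and lists of different stages 0.359, a difference of 0.295. The 3 splits of 4 lists cannot give an exact p below 0.333, which was the value found. P56 replicate 2 belongs to the LPAN series; among the 3 other lists, the E11.5 replicates had an index of 0.667 and the pairs across stages 0.331. Labels do not say whether replicates came from separate animals or pools. The p-values therefore speak only for these libraries and do not measure the spread between animals.

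Elements marked at all 3 prenatal stages and none of the 4 postnatal stages, or the reverse, were counted in each tissue. In forebrain, 84 elements were prenatal-only and 674 postnatal-only; in heart, 85 and 818; in liver, 320 and 504. With E11.5 replicate 2 in place of replicate 1, the counts were 56 and 688 in forebrain and 76 and 881 in heart. With P56 replicate 2 they were 89 and 633 in forebrain. Peaks in both replicates gave 47 and 626 in forebrain and 65 and 901 in heart. Peaks in either replicate gave 91 and 693 in forebrain and 96 and 798 in heart. With equal list lengths the counts were 322 and 358 in forebrain, 228 and 110 in heart and 348 and 286 in liver. The length was that of each tissue's shortest list, 15246 peaks in forebrain, 7376 in heart and 12474 in liver. These counts are therefore not matched across tissues. Without the heart P21 list, at equal lengths of the 6 others, a combination chosen after seeing the data, the heart counts were 574 and 1065. Among the 35 splits of the 7 lists into 3 and 4, 4 gave as many elements as the real split in forebrain, 2 in heart and 3 in liver, the real split included. Without P21 the counts were 88 and 2382 in forebrain and 98 and 3650 in heart. The real split gave the highest of 10 in both, the smallest share that 10 splits can give. In both tissues each postnatal list left was longer than each prenatal list, so that length alone could favour this split. At equal lengths without heart P21, the real split in heart was again the highest of 10, with 315 for the highest other. Forebrain without P21 was not run at equal lengths. In liver without P21 the counts were 322 and 578, and 2 of 10 splits gave as many, with 1691 for the highest other. Without peaks overlapping any input peak, the liver counts were 339 and 80, and with the heart P21 input list left out of that filter 320 and 505. With peaks trimmed to 1 kb, the heart counts were 694 and 734. Where a peak had to cover 50% of its element, chosen after seeing the data, the counts were 48 and 309 in forebrain, 93 and 460 in heart and 479 and 285 in liver. The mean Jaccard index within the prenatal or the postnatal lists exceeded that between them by 0.0444 in forebrain, 0.0482 in heart and 0.0982 in liver. Two-sided exact permutation of the differences between tissues gave adjusted p = 0.6 for forebrain against liver, 0.686 for heart against liver and 0.971 for forebrain against heart. With 35 joint splits the smallest p is 0.0286, or 0.0857 adjusted if 1 pair alone differed, so that such a pair could not have passed.

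The highest ranked prenatal-only elements in forebrain lay on chromosome 3 from 90095100 to 90100331, chromosome 14 from 21211657 to 21214097, chromosome 1 from 178851592 to 178854928, chromosome 3 from 127332897 to 127338473 and chromosome 4 from 116853652 to 116856401. The postnatal-only ones lay on chromosome 11 from 83083322 to 83086652, chromosome 8 from 74683671 to 74686566, chromosome 9 from 62257866 to 62276196, chromosome 11 from 103508961 to 103519472 and chromosome 11 from 120507500 to 120510820. Their first members had mean rank percentiles of 91.9 and 96.3. In heart, the prenatal-only elements were on chromosome 5 from 134657925 to 134661561, chromosome 2 from 163462443 to 163473265, chromosome 15 from 99799856 to 99810620, chromosome 8 from 86705858 to 86709358 and chromosome 15 from 84542363 to 84547175. The postnatal-only elements were on chromosome 5 from 17483106 to 17520328, chromosome 14 from 59417049 to 59425620, chromosome 12 from 37439550 to 37454057, chromosome 18 from 68743955 to 68752977 and chromosome 11 from 80520310 to 80533807. Percentiles of the first members were 94.7 and 82.2, and the heart postnatal-only elements needed a peak in the short P21 list. In liver, the prenatal-only elements were on chromosome 10 from 92529535 to 92536671, chromosome X from 20192723 to 20197314, chromosome 11 from 95863030 to 95871144, chromosome 2 from 13520712 to 13528998 and chromosome 2 from 31964479 to 31972919. The postnatal-only elements were on chromosome 16 from 4681921 to 4686397, chromosome 2 from 172946964 to 172955773, chromosome 8 from 34490960 to 34498002, chromosome 6 from 120769035 to 120774816 and chromosome 2 from 64839706 to 64855291. Percentiles of the first members were 73.0 and 91.6.

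Input lists gave the background. Of the 24 input lists, 22 held 17 to 42 peaks, with a median of 28, while liver P0 input held 865 and heart P21 input 23762. In the 22 other pairs, between 0 and 15 H3K27ac peaks overlapped a peak of their own input. At liver P0, 499 of 19523 peaks did (2.56%, exact binomial 95% interval 2.34 to 2.79), and at heart P21, 1091 of 7376 (14.8%, 14.0 to 15.6).

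**Figure D4:**
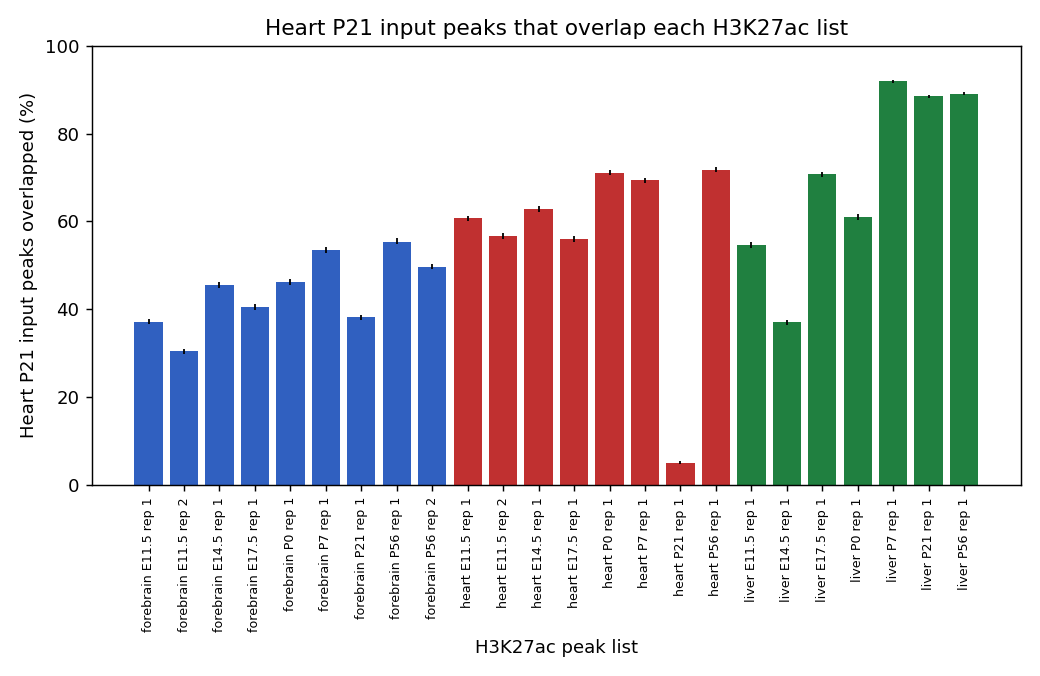
Share of the 23762 peaks of the heart P21 input list (vertical axis, percent, with exact binomial 95% intervals) that overlap a peak of each H3K27ac list (horizontal axis), coloured by tissue. The liver P7, P21 and P56 lists overlap 92.0%, 88.5% and 89.1% of them, and the heart P21 H3K27ac list 4.97%.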

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

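All explanations in this part were tested after the values that bear on them had been seen, except the relabellings of Fisher's exact test. The heart P21 input library held 23762 peaks, far above the 17 to 42 of 22 other inputs, and the liver P0 input library held 865. Input DNA has not been immunoprecipitated, so no biological explanation was tested for it.

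For heart P21 input, low depth alone is argued against: of the 2 input libraries with no more reads, the longer list held 865 peaks. DNA enriched for heart H3K27ac is argued against as well, since 0.289% (exact binomial 95% interval 0.149 to 0.504) of 4157 heart-only elements, marked at heart P7 and P56 and in no liver or forebrain list, had an input peak. Of 2418 liver-only elements, marked at liver P7, P21 and P56 and in no heart or forebrain list (heart P21 left out of both definitions), 73.3% (71.5 to 75.0) had one. A candidate explanation is therefore that this library holds DNA enriched for liver H3K27ac, through a mixed or mislabelled tube or index. Whether it was mixing or mislabelling stays open.

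The heart P21 H3K27ac list was short, with 7376 peaks, and unlike its neighbours. Among 15472 elements marked at the 6 other heart stages, 12.6% (12 to 13.2) had a P21 peak where the P21 input list had one and 45.1% (43.6 to 46.6) where it had none, a ratio of 3.59. This is consistent with peaks lost in the comparison with that input, though 45.1% is also below the 89.4% to 99.6% at which each other heart stage held the elements found at the remaining 5, P21 left out, so that another part may remain. Low depth as the whole cause is argued against by liver P0, with fewer reads and 19523 peaks. The authors' table counted 23852 peaks for this library, 16476 more than its list holds. The next largest such difference was 5133, at liver P21, so that much of the shortness arose between that count and the list. The filter between them is not stated. For the rest, a change of the heart at P21 stays open, untested.

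In liver, the split of the 7 lists between P0 and P7 parted 3953 elements, 3798 of them marked only at P7, P21 and P56, against 824 for the split at birth. Unequal list length is argued against only for where the split falls: at equal length the split between P0 and P7 gave 1184 elements and the highest other split 634. For the excess of late elements list length stays open: the excess was absent at equal length, where 549 were late and 635 early. Low depth at P0, the H3K27ac library with the fewest reads, stays open: of the elements of all 3 prenatal lists absent from P7, P21 and P56, P0 held 64.6% (61.5 to 67.6) at equal length but 32.6% (28.4 to 37.1) at full length, and these shares are built from the counts of the splits themselves. All liver libraries are of 1 name series, and stage itself, including changes in cell composition of the liver after birth, may account for the pattern, as a hypothesis.

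Chance was not excluded for the prenatal-only and postnatal-only counts over the full lists. The splits cannot decide it there, since these lists differ in length. In forebrain, 4 of 35 splits gave at least the real 758, and the highest was 1712, for P0, P7 and P56 against the rest. In heart, 2 of 35 gave at least 903, and the highest was 2845, for the same split. In liver, 3 of 35 gave at least 824, and the highest was 3953. Splits that count several times the real number point to a structure of the lists: the forebrain and heart ones set the short P21 list apart from P0, P7 and P56. At equal list length, 1 of 35 splits, the real one, gave as many as 680 in forebrain, where the highest other gave 660, while 2 of 35 gave at least 338 in heart and 2 of 35 at least 634 in liver. The planned restriction test called 0 elements for the real labels, so that 100 of 100 relabellings within stages gave as many in each tissue. By Fisher's exact test, 1 of 100 relabellings, the real one, gave as many as 2890 in forebrain, 3024 in heart and 1524 in liver. The highest other count was 0 in each. This argues against a chance assignment of tissue labels for the counts as a whole, not for each element called. It cannot separate tissue from library series, since the forebrain lists used are all IO and the liver lists all LPAN.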

How the results depend on the processing

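Alternatives with 50% of the element covered, a correction over every element and tissue, removal of input peaks other than heart P21's, and those combining a missing P21 with Fisher's exact test or equal lengths were chosen after seeing the data. Of 165 alternative values, 140 kept their direction and side of the threshold or stayed within 1.5 times the count, 28 of them by construction because the lists used did not change, and no difference changed sign. Others of the 140 could not have passed the threshold. Forebrain E11.5 against P56 cannot give a p below 0.333, and a correction over more tests cannot raise a count of 0. Tissue separation and liver ordering kept their calls in each one run. Prenatal-only and postnatal-only elements were compared by the sum of both counts, so that a shift between them could pass as kept. In forebrain at equal length the sum went from 758 to 680, kept by that rule. Its parts went from 84 and 674 to 322 and 358. The balance of prenatal-only to postnatal-only elements did turn, from 85 and 818 to 228 and 110 in heart at equal length (574 and 1065 when heart P21 was also left out). In liver it turned from 320 and 504 to 348 and 286 at equal length and 479 and 285 with 50% of the element covered. Without peaks overlapping any input peak the liver counts were 339 and 80, but 320 and 505 with the heart P21 input list left out of that filter. That turn rests on the heart P21 input list. This list overlapped 64.5% to 69% of the peaks of the prenatal liver lists and 59.5% to 74.9% of those of the postnatal ones. Such shares do not show why mainly postnatal-only elements were lost. The 50% overlap of the shorter interval changes nothing, since peaks lie inside their elements, and a score of 100 could not be applied without scores. Results on promoters, genes and gene lists were not run.

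Unless construction shows it, the cause was not tested. Without P21, or without heart P21 alone, heart ordering rose to 0.102 and passed, and the prenatal-only and postnatal-only count was 3748 in heart and, without P21, 2470 in forebrain; fewer lists must then lack or hold a peak. Without heart P21 at equal lengths, heart ordering was 0.118 and the count 1639. Equal lengths gave 338 in heart and trimming to 1 kb 1428. Covering 50% of the element gave 357 in forebrain and 553 in heart and took forebrain ordering to 0.0526, not called. With replicate 2 in place of replicate 1, forebrain ordering ranged from 0.0621 to 0.0817, not called at 0.0649. Turnover passed with trimming (0.149) and without peaks overlapping any input peak (0.162). The latter took the liver count to 419 and called 1377, 1417 and 58 restricted elements in forebrain, heart and liver, with 101735 tests in place of 139733. With the heart P21 input left out of the filter these were 0.137 (not passed), 825, and 0, 0 and 0, so that the changes rest on that list. Fisher's exact test called 2890, 3024 and 1524, and without P21 2629, 3068 and 734.

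With replicate number as a block, forebrain E11.5 against P56 gave 0.294, against 0.295 without. Deviations of same-numbered replicates had a correlation of -1.38e-05 across elements, and the replicates share only a number. Depth was lowest at liver P0 and heart P21, with 4108135 and 4644972 uniquely mapped reads.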

Other observations

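All tests in this part were chosen after the data were seen. Of the elements, 362 had a peak in all 21 lists, and 5553 in the 20 lists other than heart P21. The median rank percentile of these 5553 lay between 66.5 and 89.8 over those 20 lists. The share of a tissue's elements that were also marked in both other tissues at the same stage, P21 left out, ran in forebrain from 30.8% (exact binomial 95% interval 30.2 to 31.3) at E14.5 to 61.0% (60.3 to 61.8) at E11.5. It ran in heart from 26.7% (26.2 to 27.2) at P0 to 45.8% (45.1 to 46.5) at E17.5, and in liver from 41.8% (41.2 to 42.5) at E17.5 to 68.2% (67.4 to 69.1) at E14.5. Each of the 3 highest shares belonged to the shortest of the tissue's 6 lists compared here, with 15823, 23210 and 12474 peaks. Over the 12474 best-ranked peaks of each list, the forebrain and heart lists had a Jaccard index of 0.520 at E11.5, 0.483 at E14.5, 0.464 at E17.5, 0.417 at P0, 0.425 at P7 and 0.455 at P56. Heart and liver had 0.575 at E11.5, 0.453 at E14.5, 0.5 at E17.5, 0.466 at P0, 0.486 at P7 and 0.458 at P56. Forebrain and liver had 0.464, 0.401, 0.426, 0.396, 0.443 and 0.394 at the same stages. P21 is left out here because the heart list is shorter, and no trend was tested over these single lists.

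Forebrain P21 held 15246 peaks, between lists of 36771 at P7 and 33178 at P56, from 24025446 uniquely mapped reads. Of its peaks, 93.9% overlapped a P7 peak and 95.3% a P56 peak, and 83.1% of the elements marked at the 6 other forebrain stages were marked there. At 12474 peaks per list its Jaccard index was 0.696 with P7 and 0.714 with P56.

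Within liver, the heart P21 input list covered 10.8% of 1826 elements marked in the liver P7 list and no other list, 9.69% of 320 for P21, 8.30% of 229 for P0 and 3.18% of 1950 for P56, against 1.24% of 644 for E11.5, 0.448% of 223 for E14.5 and 1.39% of 722 for E17.5.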
